A study of Mus musculus with 6 samples.

How the data were processed

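Total RNA of mouse embryonic stem cell lines was measured on 6 Agilent whole mouse genome arrays with 1 colour (Cy3), 2 arrays in each of 3 groups, from cells grown on gelatin with serum and LIF. The wild-type lines were not transduced, and the knockout lines, which lack Dppa2 and are homozygous for a conditional targeted allele of Dppa4, carried a piggyBac vector with the CAG promoter that was either empty (mock) or made Flag-Dppa2. Both comparisons with wild type therefore also contain the transduction and the Dppa4 allele. The background was mixed 129Sv and C57BL6, per the labels.

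Per the file headers, the intensity values were extracted with Agilent Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09, which subtracts the local background, removes spatial trends within the array and puts surrogates in place of very dim spots, on a linear scale without scaling between arrays. The log2 values of the series matrix as deposited were made by the authors with GeneSpring GX 11, and they are quantile-normalized without centring. Their column medians were 5.84, 5.84, 5.84, 5.85, 5.86 and 5.85, and their correlations with the scanner's log2 values were above 0.999. The scanner's intensity values were used for the main analysis and the log2 values of the authors for 1 alternative. The headers name genome build mm9, so no coordinates are given.

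Each array held 45018 spots, of which 1639 control spots were left out. Spots with an outlier flag were left out as well, the log2 signals of the other spots of a probe were averaged, and 115 of 41174 probes with no such spot on some array were dropped, which left 41059. Between 55.9% and 60.4% of the probes were well above background per array, the 75th percentile of the signal was 719 to 856 intensity units, and no spot was saturated. The median SD between spots of a probe was 0.06 to 0.07 (log2). Probes were named through the RefSeq accessions in the files and a reference table of assembly GRCm38, used only for names and chromosomes. This gave 27143 probes 1 of 18516 symbols and left 13916 without a symbol.

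The 75th percentile of each array was subtracted from its log2 signals. Probes well above background on at least 2 of the 6 arrays were kept, with 1 probe per symbol, the one with the highest mean, which left 13307 genes and 5467 probes without a symbol. All 6 arrays went into 1 limma fit of the 3 groups (limma 3.58.1 in R 4.3.3, statmod 1.5.0, lmFit and eBayes, prior degrees of freedom 1.41, residual 3), and a gene or probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 18774 features of a comparison, two-sided. Differences are given in log2 with the SE of the fit. Where a gene was not well above background on either array of a group, a lower bound of the fold is given, and where it was below background in both groups no fold is given. Figures and array pairs were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

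Array pairs were compared over 14986 spots with a signal of at least 200 on all arrays, with the limit at 1.96 times the scanner's error of the difference, and over 128 probes with at least 10 spots. The replicate number pairs mock with Flag-Dppa2 arrays of the same line, and wild type shares only the mother. The correlations of the arrays' deviations from their group means between same-numbered arrays were -0.04 for wild type and mock, 0.01 for wild type and Flag-Dppa2, and 0.59 for mock and Flag-Dppa2, over 18774 features. The planned fit had no block and was kept. Values with the replicate as a block are given beside the total counts and list tests that they change, and for single genes only for Dppa2. This block gives all 3 groups the same shift between replicates, which the wild-type arrays did not share with the knockout arrays.

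The 22 gene lists, the comparisons, the tests and most alternatives were fixed before the data were examined, apart from X-linked genes, whose list was taken from the reference table by a rule fixed then. The lists hold naive pluripotency, formative and primed pluripotency, two-cell-like, germline and meiosis, endoderm, mesoderm and cardiac, neural ectoderm, trophectoderm, Hox, lung development, DNA methylation, imprinted, Y-linked, X-linked, chromosome 16 neighbours of Dppa2 and Dppa4, fibroblast and feeder, p53 target, proliferation, interferon, immediate-early and heat shock, hypoxia and glycolysis, and cholesterol synthesis genes. They were tested with camera of limma at a preset correlation of 0.01, adjusted over all 66 tests, and again with an estimated correlation. With an estimated correlation camera tests on the residual degrees of freedom, 3 here, so small p-values grow even where that correlation is under 0.01. A list that does not pass there is thus not shown to fail through correlation between its genes. Members are counted as called over all genes, and also after adjustment over the list alone.

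Named genes follow a fixed rule: Dppa2, Dppa4, Nkx2-5 and Syce1, the 10 highest and 10 lowest called genes per comparison with the same sign in both same-numbered pairs, the 5 largest in each class of changed-back and not changed-back genes, and the 4 list members with the smallest p. Clone and predicted-gene names were passed over in the first parts, and some list members that the rule names are not reported here. For genes changed back, unchanged groups that share the mock arrays were simulated 100 times for the covariance and 20 times with tests. The simulated arrays were independent, with 1 spread per gene for all groups. The pipeline was tested on simulated data with 200 of 18774 features changed. It called 20 of 67 features at a log2 change of 1, 47 of 67 at 2 and 50 of 66 at 4, with 8 false calls among 125 and 0 calls in the unchanged comparison. These simulated arrays were also independent, with 1 spread per gene for all groups, unlike the measured arrays. The shares found and the false calls are therefore no measure of the error rate in these data.

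The alternatives were quantile normalization, normexp background correction (offset 50), a floor for dim values, no filter and a filter on all 6 arrays, the replicate and the slide as a block, every probe or the mean over probes, eBayes with a trend or robust, a 2-fold minimum, the series matrix, only the groups compared, and each array left out. Normexp was planned on the mean spot signal and run on the median spot signal, since the columns used hold the median. Added after seeing the data were the wild-type arrays averaged into 1 sample, the cell line as a random block, and the 4 knockout arrays with the replicate block.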

Results

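Gene expression was measured in mouse embryonic stem cells that lack Dppa2, a SAP-domain protein of pluripotent cells and the germline that is also called ECAT15-2. There were 3 groups of 2 arrays, each array labelled as a sample of its own. The wild-type lines carried no vector, the mock knockout lines lacked Dppa2 and carried an empty piggyBac vector, and the Flag-Dppa2 knockout lines were the same knockout lines with a vector that makes Flag-tagged Dppa2. The knockout lines also carry a conditional targeted allele of Dppa4, the paralogue and neighbour of Dppa2, on both chromosomes, and the wild-type lines do not. Replicates 1 and 2 came from blastocysts of different mothers, so that mock and Flag-Dppa2 arrays of the same number share a knockout line. The arrays had 55.9% to 60.4% of their 41174 probes well above background and no saturated spot. The 75th percentile of the signal lay between 719 and 856 intensity units, and the number of arrays limits the precision. All levels below are log2 signals relative to that percentile of the array.

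The 2 wild-type arrays differed by less than the scanner's error estimate, which does not settle whether they are 1 sample or 2. Of 14986 bright spots, 8 differed by more than 2-fold between them, and 0.487% differed by more than the 95% limit of the scanner's error estimate, where 5% are due. The corresponding shares were 22.6% between the mock arrays, with 540 spots over 2-fold, and 25.01% between the Flag-Dppa2 arrays, with 473 spots over 2-fold. Of 128 probes printed in 10 or more spots, 21.1% differed between the wild-type arrays, against 89.8% between the mock and 89.1% between the Flag-Dppa2 arrays. By chance 5% are due if the spots of an array are independent. The median SD within a group over 15925 features well above background on all arrays was 0.04 in wild type, 0.15 in mock and 0.17 in Flag-Dppa2. Wild-type levels are therefore given as the mean of 2 arrays without an error, and knockout levels as mean ± SD (n = 2). The planned limma fit over all 6 arrays takes the wild-type arrays as 2 samples and assumes one spread for all groups, so its adjusted p-values are too small where these arrays are 1 sample. Even if they are 2, their small spread lowers the shared estimate that is used for Flag-Dppa2 against mock. There the planned fit called 119 genes, and limma on only the 4 knockout arrays, with fewer degrees of freedom, called 0. The correlation of 0.59 between mock and Flag-Dppa2 deviations, which the planned fit leaves out, acts the other way. The labels give them different mothers. The 21.1% of probes that differed between them exceeds 5%, but the spots of an array share its labelling and hybridization. The same RNA on 2 arrays could therefore also exceed 5%, so this share does not decide. The share of 0.487%, under the 5% due, also means that the scanner's error was a wide measure for this pair. Whether they are 1 sample stays open. Genes are called higher or lower from that fit. Each comparison's total of called genes, and the number changed back, is followed by the count with the wild-type arrays averaged into 1 sample, which was added after seeing the data. No gene or probe passed with that averaging in any comparison, so 0 list members would be called over all genes as well.

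**Figure D1:**
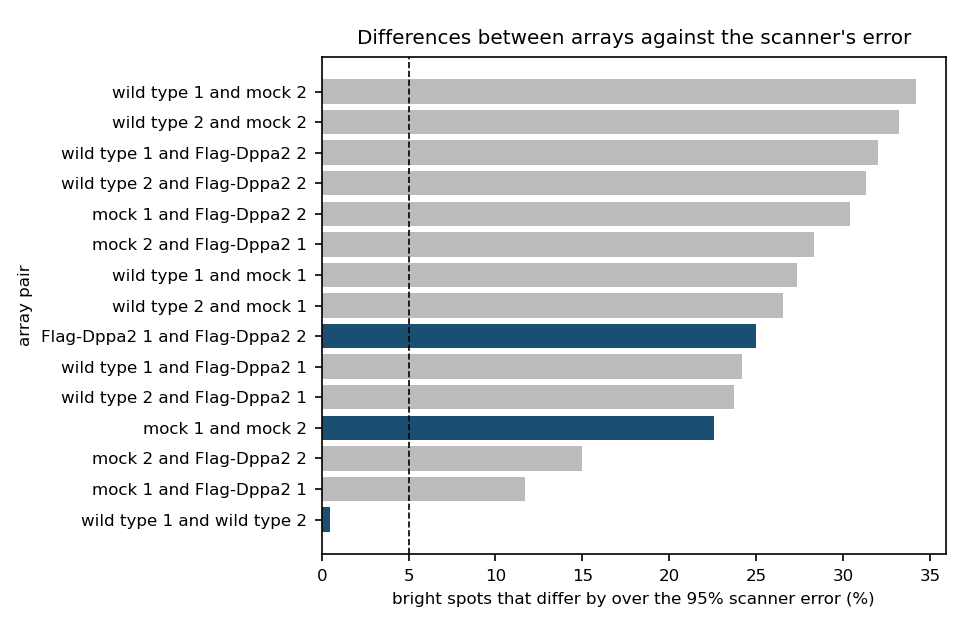
Share of 14986 bright spots (x axis, %) whose difference between the 2 arrays of a pair (y axis) exceeds the 95% limit of the scanner's error, with dark bars for arrays of the same group and a dashed line at the 5% due. The wild-type pair lies at 0.487%, and every other pair lies above the line, from 11.7% for mock and Flag-Dppa2 replicate 1 to 34.2% for wild type 1 and mock 2.

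The first comparison, mock knockout against wild type, asks what the loss of Dppa2 changes. Dppa2 itself was called 17.7-fold lower in the mock knockout, at -2.05 ± 0.06 (SD, n = 2) against 2.10 in wild type (log2 difference -4.15, SE 0.16, adjusted p = 0.00565). Its probe stayed well above background on both mock arrays, and whether the probe lies inside the deleted part of the gene, or in the sequence that the vector carries, was not checked. Dppa4 stood at 3.57 ± 0.14 (SD, n = 2) against 2.98 and was not called (adjusted p = 0.0698). Genes of the germline and of meiosis were among those called lower by wide margins. Syce1, a component of the synaptonemal complex, was called at least 226-fold lower (adjusted p = 0.00783), Psma8, the proteasome subunit of male germ cells, at least 262-fold lower (adjusted p = 0.00176), Ddx4, the germ cell RNA helicase Vasa, at least 144-fold lower (adjusted p = 0.0272), and Mael, a factor of transposon silencing in germ cells, at least 102-fold lower (adjusted p = 0.0341). These 4 genes were well above background on both wild-type arrays and on neither mock array. Such a bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background.

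Of the 36 germline and meiosis genes tested, 18 were called lower and none higher, and adjusted over the list alone 19 were lower and 1 higher. Among them, Taf7l, a germ cell transcription factor, was at least 17.8-fold lower, Stk31 was at least 13.2-fold lower, and Smc1b, the meiotic cohesin subunit, had a log2 difference of -4.09 (SE 0.29). The list's median was -1.55, and camera gave an adjusted p of 1.03e-10, with adjusted p = 0.26 with an estimated correlation. Of 11 genes of the two-cell-like state, 7 were called lower (8 adjusted over the list alone), with a median of -3.31, or -2.98 with genes below background at their bounds. Examples were Zscan4c, a telomere factor of that state, at least 49.2-fold lower, Gm428 at least 37.9-fold lower, Usp17la at least 17.8-fold lower and Tcstv1 at least 7.26-fold lower. The list's adjusted p was 5.2e-05, and 0.26 as adjusted p with an estimated correlation. All 3 tested Y-linked genes were called lower, also adjusted over the list alone. Eif2s3y, a translation factor subunit, was at least 474-fold lower, the RNA helicase Ddx3y at least 94.1-fold lower and the zinc finger gene Zfy2 at least 4.51-fold lower (list adjusted p = 1.82e-05, adjusted p = 0.26 with an estimated correlation). Both wild-type arrays thus carried Y-linked transcripts and none of the 4 knockout arrays had them above background, so sex and genotype cannot be told apart in either comparison with wild type.

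Fibroblast and feeder cell markers lay lower in the mock knockout, with a median of -2.12 over 24 genes (-0.94 in line 1 and -2.97 in line 2), and of -0.56 with normexp background correction. That correction also brought the medians of the germline list to -0.81, of the two-cell-like list to -1.32, of the interferon list to -0.58 and of the Y-linked list to -3.27, and all 5 lists passed with it. The members called were Loxl1, a collagen cross-linking enzyme, at least 20.4-fold lower, the gelatinase Mmp2, 19.4-fold lower, and Fbn1, the microfibril protein fibrillin, at least 10.3-fold lower, and 4 members were lower adjusted over the list alone. The list's adjusted p was 5.87e-05 (adjusted p = 0.525 with an estimated correlation). The formative and primed pluripotency list had a median of -0.75, with -0.64 in line 1 and -1.48 in line 2 (list adjusted p = 0.00729, adjusted p = 0.525 with an estimated correlation). Of its 17 genes, 4 were called lower (6 adjusted over the list alone). These were Fgf5, 12.4-fold lower, Fgf8, 6.89-fold lower, Zic2, at least 4.2-fold lower, and the DNA methyltransferase Dnmt3b, 1.65-fold lower. Of 26 naive pluripotency genes, 3 were called higher, Nr0b1 (1.99-fold), Utf1 (1.83-fold) and the adhesion protein gene Jam2 (1.58-fold), and none lower. Adjusted over the list alone, 6 were higher and 1 lower, the median was 0.34, and the list's adjusted p was 0.00209 (adjusted p = 0.318 with an estimated correlation). Of 23 interferon response genes, 5 were called lower, and 11 lower and 2 higher adjusted over the list alone, with a median of -1.04. Psmb8, a subunit of the immunoproteasome, was at least 112-fold lower, the viral RNA sensor Ifih1 at least 5.76-fold, Ifi35 3.35-fold and the transcription factor Irf1 2.72-fold lower (list adjusted p = 0.00979, adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis genes had a median of 0.45 over 23 members, with 0.19 in line 1 and 0.59 in line 2. Mvk, a kinase of the mevalonate pathway, was called 2.03-fold higher and 1 member was called lower. Adjusted over the list alone, 5 were higher and 1 lower (list adjusted p = 0.00142, adjusted p = 0.611 with an estimated correlation).

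The 14 tested neighbours of Dppa2 and Dppa4 on chromosome 16 had a median of -0.47 with none called (6 lower and 1 higher adjusted over the list alone). A dimmer probe of the neighbour Slc35a5, a sugar transporter gene, lay at -2.28 and passed when every probe was tested (adjusted p = 0.00678), while the probe used lay at -0.74 (adjusted p = 0.0501). The list's adjusted p was 0.0472, 0.331 as adjusted p with an estimated correlation and 0.0533 within the first slide. Nkx2-5, a cardiac transcription factor, was called at least 9.25-fold lower (adjusted p = 0.0437), from -2.85 to a level not above background. In its list of 22 mesoderm and cardiac genes, 2 were called higher and 4 lower (2 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.0519, and 0.0385 with normexp). Mesp2 and Myh6 were also among the lower members, Myh6 above background on 1 of 2 mock arrays, and Isl1 was called 3.35-fold higher, with 1 of 2 wild-type arrays above background.

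Several transcription factor genes were called higher in the mock knockout. Barx1 was called at least 17.8-fold, Dmbx1 15.7-fold, Zic1 at least 10.8-fold and Lhx5 at least 4.88-fold higher (adjusted p from 0.0303 to 0.0491), although a dimmer probe of Dmbx1 stood at 0.95 and was not called. Dimmer probes of Zic1, Mvk, Jam2, Ccne1 and Abca3 likewise lay higher and were not called. Mag, a myelin glycoprotein gene, was 11.4-fold higher (adjusted p = 0.018), and Abca1, the cholesterol efflux transporter, 10.9-fold higher (adjusted p = 0.00783). The protocadherin gene Pcdhb14 was at least 7.1-fold, Olfr164, an olfactory receptor gene, at least 6.94-fold, Gdpd4 at least 6.09-fold and the helicase gene Helz2 5.5-fold higher. Other genes called lower by wide margins were Reg2, at least 133-fold, Car4, a carbonic anhydrase, at least 110-fold, Tescl, at least 96.2-fold, and Aga, a lysosomal amidase, at least 95.6-fold lower.

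The remaining 12 lists did not pass in this comparison, with adjusted p from 0.0519 to 0.864. Hox genes had a median of 0.86 with 1 of 11 called, Hoxa9, at least 1.9-fold higher (3 higher and 1 lower adjusted over the list alone). Of 26 p53 targets, Gadd45a was called 2.13-fold higher, also alone in its list adjusted over the list alone. With the replicate block, the Hox and p53 lists passed (adjusted p = 0.0328 and 0.0367). The Hox list also passed with the wild-type arrays averaged (adjusted p = 0.044), with quantile normalization (0.0176) and in the series matrix (0.0171), and the p53 list in none of these (0.0508, 0.179 and 0.182). Neither passed with normexp (adjusted p = 0.0553 and 0.0817). Imprinted genes had 5 called higher and 3 lower of 35 (6 and 6 adjusted over the list alone), among them Cdkn1c, a cyclin-dependent kinase inhibitor, 2.54-fold higher, Peg3 3.47-fold lower and Gatm at least 13.3-fold lower. Neural ectoderm genes had 3 higher and 1 lower of 24, in the same number adjusted over the list alone, with Lhx2 2.46-fold higher and the intermediate filament gene Nes 3.29-fold lower. X-linked genes had 12 higher and 31 lower of 451 (17 and 40 adjusted over the list alone) and a median of -0.02. DNA methylation genes had 1 higher, Mbd1, and 1 lower, Dnmt3b, of 24 (3 and 3 adjusted over the list alone). Endoderm genes had 1 lower of 21, Amn, 8.17-fold (2 and 2 adjusted over the list alone). Hypoxia and glycolysis genes had 1 higher, Kdm3a, and 1 lower, Egln3, of 27 (2 and 3), trophectoderm genes had 1 higher, Tead4, of 18 (1 and 1), and proliferation genes 1 higher, Ccne1, of 26 (1 and 0 adjusted over the list alone). Immediate-early and heat shock genes had 2 higher of 22, Nr4a1 and Hsph1 (3 and 3), with a median of 0.05 and a mean of -0.08. Lung development genes had 2 higher of 18, Abca3 and Bmp4 (3 and 1), with a median of -0.15, a mean of 0.01 and a test direction of lower.

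In all, 892 of 13307 genes were called, 350 higher and 542 lower, along with 114 higher and 146 lower of 5467 probes without a gene symbol. Of the called genes, 198 had only a bound, and 566 differed by at least 2-fold. With the wild-type arrays averaged into 1 sample, limma called 0 genes, with a smallest adjusted p of 0.122. In that fit 1696 genes had an unadjusted p under 0.05 against 665 due by chance, and the 892 called genes were all among them. It holds the same log2 differences and the same knockout arrays, so this is no separate support for the calls. Leaving out either wild-type array left 0 called genes, leaving out mock replicate 1 left 286 and mock replicate 2 left 310, the replicate block left 390 (72 higher and 318 lower), and the fit within the first slide, which holds all arrays of this comparison, called 709 (209 higher and 500 lower). The shares of higher and lower genes moved with the filter and the model: 457 were higher and 427 lower among genes well above background on all 6 arrays, and 709 higher and 757 lower with an intensity trend.

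**Figure D2:**
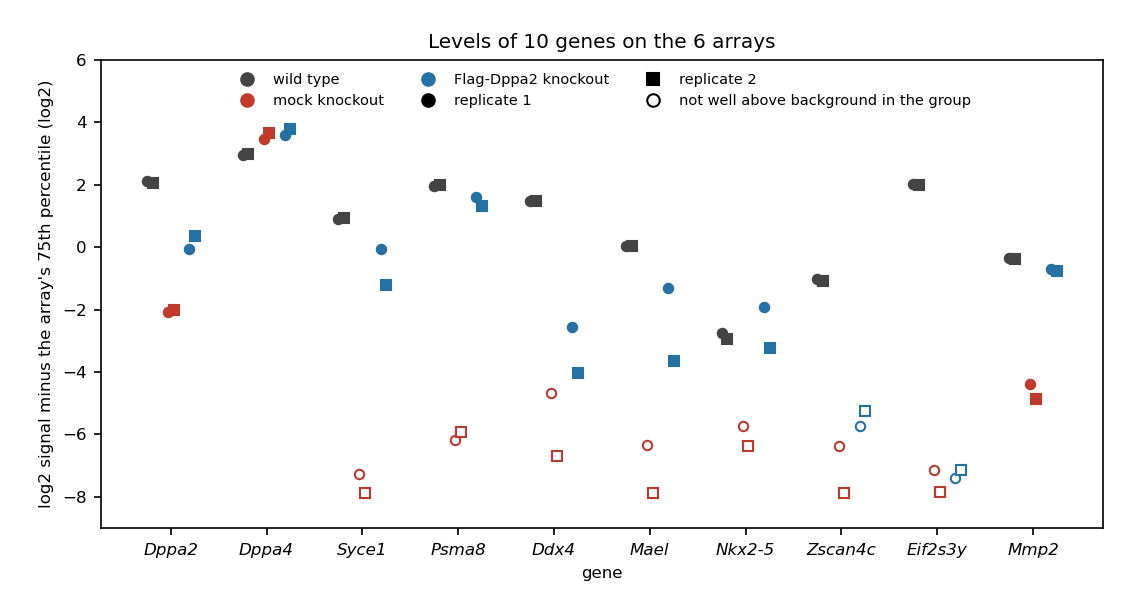
Log2 signal relative to the array's 75th percentile (y axis) of 10 genes (x axis) on each of the 6 arrays, with open symbols where the probe was not well above background in the group. Syce1 and Psma8 lie below background on both mock arrays and return with Flag-Dppa2, while Eif2s3y lies below background on all 4 knockout arrays, and levels of different genes are not comparable.

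The second comparison, Flag-Dppa2 against mock knockout, asks what returning Dppa2 changes within the same knockout lines. Dppa2 was called 4.59-fold higher with the vector, at 0.15 ± 0.29 (SD, n = 2) against -2.05 ± 0.06 (SD, n = 2) (log2 difference 2.20, SE 0.16, adjusted p = 0.0268, and 0.0667 with the replicate block). The germ cell genes Psma8 and Syce1 were called at least 182-fold and at least 76.6-fold higher (adjusted p = 0.004 and 0.022). Aga, the lysosomal amidase, was at least 162-fold higher (adjusted p = 0.0166), Prxl2a, a peroxiredoxin-like gene, 79.9-fold (log2 difference 6.32, SE 0.31), the lysosomal protease gene Ctsh at least 56.2-fold, and Fam149a at least 51.2-fold higher. Hmgn3, a nucleosome-binding protein gene, was at least 38.2-fold, Upb1, an enzyme of pyrimidine breakdown, at least 32.3-fold, the gasdermin gene Gsdme at least 29-fold and the X-linked homeobox gene Rhox13 at least 25.9-fold higher. The 4 genes called lower were Gdpd4, at least 6.91-fold, Helz2, 6.51-fold (log2 difference -2.70, SE 0.15), the proteoglycan gene Ncan, 2.32-fold (-1.22, SE 0.09), and the kinase gene Taok3, 1.96-fold (-0.97, SE 0.10). For Taok3, a dimmer probe had a log2 difference of 0.58 and was not called. With the replicate block, 3 genes were called higher and 0 lower in this comparison, so most genes named here lost their call. That block also covers the wild-type arrays, which did not share the shift between the knockout lines. Limma on only the 4 knockout arrays called 0 genes with or without the block. Unadjusted p-values under 0.05 numbered 2601 with it and 1072 without, so the lost calls are no measure of the pairing alone. Nkx2-5 stood at -2.57 ± 0.93 (SD, n = 2), at least 11.2-fold above the mock level, and was not called (adjusted p = 0.0899).

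Germline and meiosis genes lay higher with Flag-Dppa2, with a median of 0.60, or 0.29 with normexp, and 4 of 36 called higher (11 adjusted over the list alone). These were Syce1, Stk31 (at least 14.1-fold), Mei1 (at least 8.77-fold) and Taf7l (at least 5.17-fold), and the list's adjusted p was 2.42e-08 (adjusted p = 0.26 with an estimated correlation). Fibroblast markers had 3 of 24 called higher, in the same number adjusted over the list alone, with a median of 0.58, or 0.37 with normexp. These were Mmp2 (15.0-fold), Fbn1 (at least 5.97-fold) and Loxl1 (at least 5.31-fold), and the list's adjusted p was 0.00179 (adjusted p = 0.567 with an estimated correlation). Cholesterol synthesis genes lay lower, with a median of -0.57 and none of 23 called, although 10 were lower adjusted over the list alone (list adjusted p = 4.35e-09, adjusted p = 0.525 with an estimated correlation). The estimated correlation of this list was 0.746, so the preset 0.01 makes its camera p too small. Among its members, Nsdhl stood at -1.09, Cyp51 at -0.97 and Hmgcs1 at -0.82.

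A further 8 lists passed with none of their members called over all genes. Those with higher medians were endoderm (0.62, adjusted p = 0.00477), trophectoderm (0.57, adjusted p = 0.0342), mesoderm and cardiac (0.43, adjusted p = 0.0342), lung development (0.39, adjusted p = 0.0173), the chromosome 16 neighbours (0.34, adjusted p = 0.00179) and formative pluripotency (0.32, adjusted p = 0.0117). With an estimated correlation their adjusted p-values were 0.525, 0.318, 0.318, 0.3, 0.26 and 0.525 in that order. Line 1 had medians of 0.84, 0.78, 0.70, 0.26, 0.32 and 0.73 in the same order, and line 2 had 0.51, 0.48, 0.17, 0.24, 0.36 and 0.21. Normexp brought the medians of the endoderm, mesoderm and neighbour lists to 0.36, 0.20 and 0.22, and all 3 passed with it. Adjusted over the list alone, 5, 0, 4, 3, 1 and 2 of their members were higher, and 1 mesoderm gene was lower. Foxa2, an endoderm transcription factor, stood 2.56-fold above mock, Cubn, an endocytic receptor gene, 8.58-fold and Gata2 3.91-fold, none of them called. Naive pluripotency genes had a median of -0.10 (adjusted p = 0.0333, adjusted p = 0.523 with an estimated correlation). In that list Pou5f1, the gene of the pluripotency factor Oct4, stood 1.48 higher and Tfcp2l1 was at -0.68, neither of them called over all genes, and 1 member was higher and 1 lower adjusted over the list alone. Hypoxia and glycolysis genes had a median of -0.22 but a mean of 0.002, with a test direction of lower (adjusted p = 0.0117, adjusted p = 0.26 with an estimated correlation). Quantile normalization ended the calls of the hypoxia, mesoderm, naive pluripotency and trophectoderm lists (adjusted p = 0.0703, 0.0662, 0.144 and 0.0568). Of the 11 lists that did not pass, imprinted, two-cell-like and X-linked genes passed with the replicate block (adjusted p = 0.0414, 0.037 and 0.0445) and with the wild-type arrays averaged (0.0492, 0.044 and 0.045). Imprinted and X-linked genes passed with quantile normalization (adjusted p = 0.0353 for both), two-cell-like genes did not (0.103), and none of the 3 passed with normexp (0.0817, 0.336 and 0.0942, in the same order). None of the 11 two-cell-like genes was called, imprinted genes had 1 of 35 called, Gatm, at least 12.3-fold higher (3 adjusted over the list alone), and X-linked genes had 7 higher of 451 (15 higher and 2 lower adjusted over the list alone), among them Mageb4, at least 22.4-fold. The p53 list had a median of -0.02 and a mean of 0.15.

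In all, 119 genes were called, 115 higher and 4 lower, 57 of them with only a bound. With the wild-type arrays averaged into 1 sample limma called 0 genes, with a smallest adjusted p of 0.0982 and 1072 unadjusted p-values under 0.05, 738 higher and 334 lower, against 665 due by chance. The 119 genes were among them, which is no separate support, as the differences and the knockout arrays are the same. A lone wild-type sample adds nothing to the estimate of the spread. For this comparison, the fits below without 1 wild-type array and of only the 4 knockout arrays are therefore this same fit, not separate checks. With the cell line as a random block, added after seeing the data, it called 1365 genes, 870 higher and 495 lower, so the split depends on the model. The mock arrays lie on the first slide and the Flag-Dppa2 arrays on the second, so slide and group cannot be told apart. Leaving out either wild-type array, or either Flag-Dppa2 array, left 0 called genes, leaving out mock replicate 1 left 29, the fit of only the 4 knockout arrays called 0 with 1072 unadjusted p-values under 0.05, and the replicate block left 3.

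Of the 542 genes called lower in the mock knockout, 106 were called higher again with Flag-Dppa2, and of the 350 called higher 4 were called lower again, 110 in all and 92.4% of the genes called with Flag-Dppa2. Independent lists would share 4.68 and 0.105 genes in these directions, and unchanged groups that share the mock arrays gave 0 in simulation. No gene was given an effect there, so this 0 is no measure for lists that hold effects. The genes called back with the largest knockout differences were Syce1, Psma8, Aga, Hmgn3 and Gsdme among the lower, and all 4 among the higher were Gdpd4, Helz2, Ncan and Taok3. The changes had opposite signs for 68.1% of all genes, against 66.6% simulated for unchanged groups that share the mock arrays. Across 13307 genes, which are not independent replicates, the covariance of the knockout change and the Flag-Dppa2 change was -0.423, against -0.098 simulated for unchanged groups, a difference of -0.324. It was -0.130 with normexp, where 41 genes were called back, and -0.181 over genes well above background on all 6 arrays, where 25 were. The simulation was not repeated for these 2. With no array shared by both differences it was -0.365. The correlation was -0.714 against -0.50 simulated, and -0.510 and -0.516 with no array shared. The simulation drew independent arrays with 1 spread per gene for all groups, unlike these data. Over features well above background on all arrays, the median SD was 0.04 in wild type, 0.15 in mock and 0.17 in Flag-Dppa2. Deviations of mock and Flag-Dppa2 arrays correlated at 0.59. The simulated covariance, correlation and share of opposite signs are therefore no exact measure of unchanged groups, and differences from them decide nothing. The calls were not repeated on split mock arrays, since each part would hold 1 array, and part of the overlap can come from sharing them. The number of genes called back was 3 with the replicate block, 0 with the wild-type arrays averaged or with either wild-type or either Flag-Dppa2 array left out, 28 without mock replicate 1, and 357 with the cell line as a random block (277 lower and then higher, 80 higher and then lower).

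**Figure D3:**
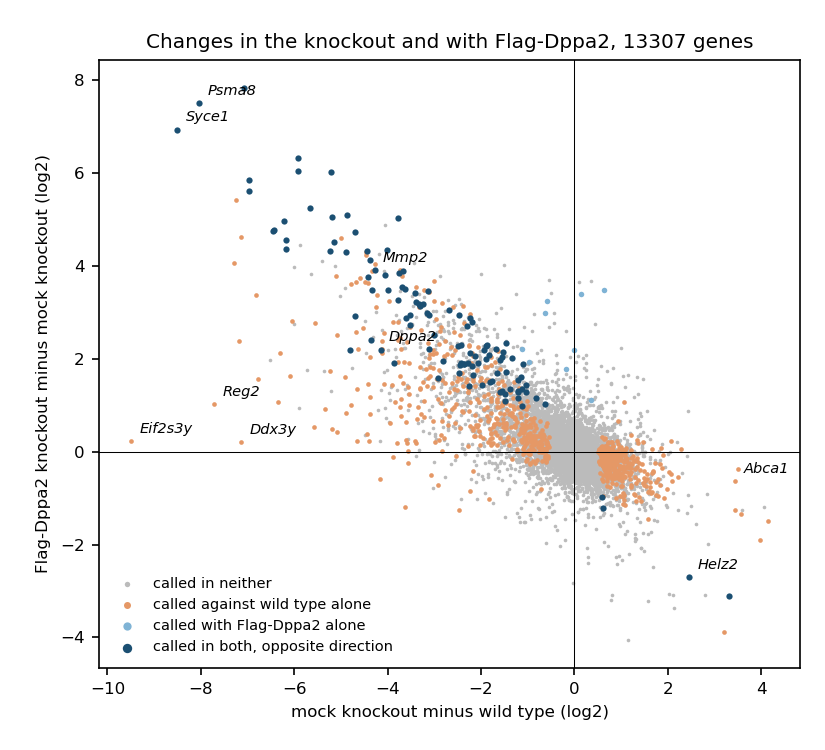
Log2 difference of mock knockout minus wild type (x axis) against Flag-Dppa2 minus mock knockout (y axis) for 13307 genes, with colours for the comparisons in which a gene was called. The 106 genes lower in the knockout and higher with Flag-Dppa2 lie at the upper left, and Eif2s3y and Ddx3y lie near 0 on the y axis, where their values are below background in both groups.

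The third comparison, Flag-Dppa2 knockout against wild type, asks what stays different after Dppa2 was returned. Dppa2 was still called 3.87-fold lower than in wild type (log2 difference -1.95, SE 0.16, adjusted p = 0.041), and Dppa4 stood 0.72 higher and was not called (adjusted p = 0.0877). Nod1, a sensor of bacterial peptidoglycan, was called 16.7-fold lower (log2 difference -4.06, SE 0.14, adjusted p = 0.0165) and Hsf5, a heat shock factor of the testis, 13.8-fold lower. Reg2 was called at least 83-fold lower, Usp17la, a deubiquitinase of the two-cell-like state, at least 26.9-fold, Speer4f1 at least 23.4-fold, the actin-binding protein gene Parva at least 21.1-fold, Pramel37 at least 12.2-fold and the transcription factor gene Twist2 at least 10.6-fold lower. Genes called higher included Mdfi, an inhibitor of myogenic factors, at least 17.3-fold, Ppp3r2, a calcineurin subunit gene, at least 11.6-fold, the transporter Abca1, 7.04-fold, and Kifc1, a mitotic kinesin, 5.44-fold. Slc35b4, a nucleotide sugar transporter, was 4.97-fold, Zfp40 4.54-fold, Olfr1133 at least 4.5-fold, Mageh1 4.38-fold, Id1, an inhibitor of DNA-binding factors, 3.81-fold and the cell cycle inhibitor Cdkn1c 3.03-fold higher, with the 2 dimmer Slc35b4 probes at 0.76 and 0.85 and not called. Nkx2-5 stood 0.28 (SE 0.50) from its wild-type level and was not called. With the replicate block, 0 genes were called in this comparison, so none of the genes named here kept its call.

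Y-linked genes were called lower again in 3 of 3 cases, with Eif2s3y at least 422-fold, Ddx3y at least 83.7-fold and Zfy2 at least 4.91-fold lower (median -6.92, or -3.36 with normexp, list adjusted p = 1.62e-06, adjusted p = 0.26 with an estimated correlation). Of 11 two-cell-like genes, 3 were called lower (7 lower and 1 higher adjusted over the list alone, median -2.49, or -1.23 with normexp). These were Usp17la, Gm428, at least 28.6-fold, and Tcstv1, at least 5.63-fold, while Zscan4c was at least 22.1-fold lower and not called (adjusted p = 0.0597), although its dimmer probe passed (-3.39, adjusted p = 0.0396). The list's adjusted p was 6.23e-05 (adjusted p = 0.26 with an estimated correlation). Germline genes had a median of -0.80, or -0.39 with normexp, with none of 36 called (12 lower adjusted over the list alone), and the list passed with an adjusted p of 3.73e-06 (adjusted p = 0.26 with an estimated correlation). Gtsf1 stood at -1.54, Smc1b at -2.63 and Tex14 at -2.11. Of 23 interferon genes, Ifi35 was called 2.93-fold lower (3 lower and 1 higher adjusted over the list alone, median -0.72, list adjusted p = 0.00179, adjusted p = 0.26 with an estimated correlation), and of 24 fibroblast markers Loxl1 was called 3.83-fold lower, also adjusted over the list alone (median -0.78, with -0.17 in line 1, -1.46 in line 2 and -0.44 with normexp, list adjusted p = 0.0064, adjusted p = 0.611 with an estimated correlation).

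With none of their members called over all genes, Hox (median 0.74), lung development (0.36) and p53 target genes (0.32) passed as higher, and hypoxia (-0.26) and cholesterol synthesis genes (-0.23) as lower. Their adjusted p-values were 0.00505, 0.0313, 0.0314, 0.00505 and 0.0489 in that order, and 0.537, 0.318, 0.611, 0.26 and 0.73 as adjusted p with an estimated correlation. In the same order, line 1 had medians of 1.25, 0.34, 0.45, -0.19 and -0.26, and line 2 had 0.64, 0.38, 0.17, -0.29 and -0.09. Adjusted over the list alone, 2 Hox, 6 lung, 1 p53 and 1 hypoxia gene were higher, and 1 lung, 2 hypoxia and 1 cholesterol gene were lower. Normexp brought the Hox and lung medians to 0.42 and 0.21, and both lists passed with it. The p53 list missed the threshold with quantile normalization (adjusted p = 0.0805) and with normexp (0.058), and the cholesterol list missed it with the wild-type arrays averaged (adjusted p = 0.0567). Naive pluripotency and endoderm genes, which did not pass, passed with the replicate block (adjusted p = 0.0491 and 0.0367). The endoderm list also passed with the wild-type arrays averaged (adjusted p = 0.0492) and with quantile normalization (0.0338), but not with normexp (0.0553), and the naive list in none of these (0.0611, 0.226 and 0.124). Median and mean differed in sign for the mesoderm (-0.03 and 0.07), neighbour (0.002 and -0.02) and X-linked lists (0.01 and -0.10), none of which passed. Of 451 X-linked genes 3 were called higher, Mageh1, Emd and Dusp9, and 3 lower (11 and 12 adjusted over the list alone), and a dimmer probe of Dusp9 was not called. Leaving out clone and predicted-gene names, the 5 genes with the largest knockout differences that were called against wild type in both comparisons and not changed back were Eif2s3y, Reg2, Ddx3y, Parva and Speer4f1.

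In all, 69 genes were called, 19 higher and 50 lower, 26 with only a bound, and 61 of them were called in the same direction in the mock knockout. With the wild-type arrays averaged limma called 0 genes, with a smallest adjusted p of 0.349 and 1051 unadjusted p-values under 0.05 against 665 due by chance. The 69 genes were among them, which again is no separate support. The replicate block, leaving out either wild-type or either Flag-Dppa2 array gave 0 called genes, either mock array left out gave 3, and the fit of only these 4 arrays gave 3. Slide and group cannot be told apart, and the split of calls moved with the scaling, to 62 higher and 94 lower with quantile normalization and 144 higher and 153 lower with normexp.

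**Figure D4:**
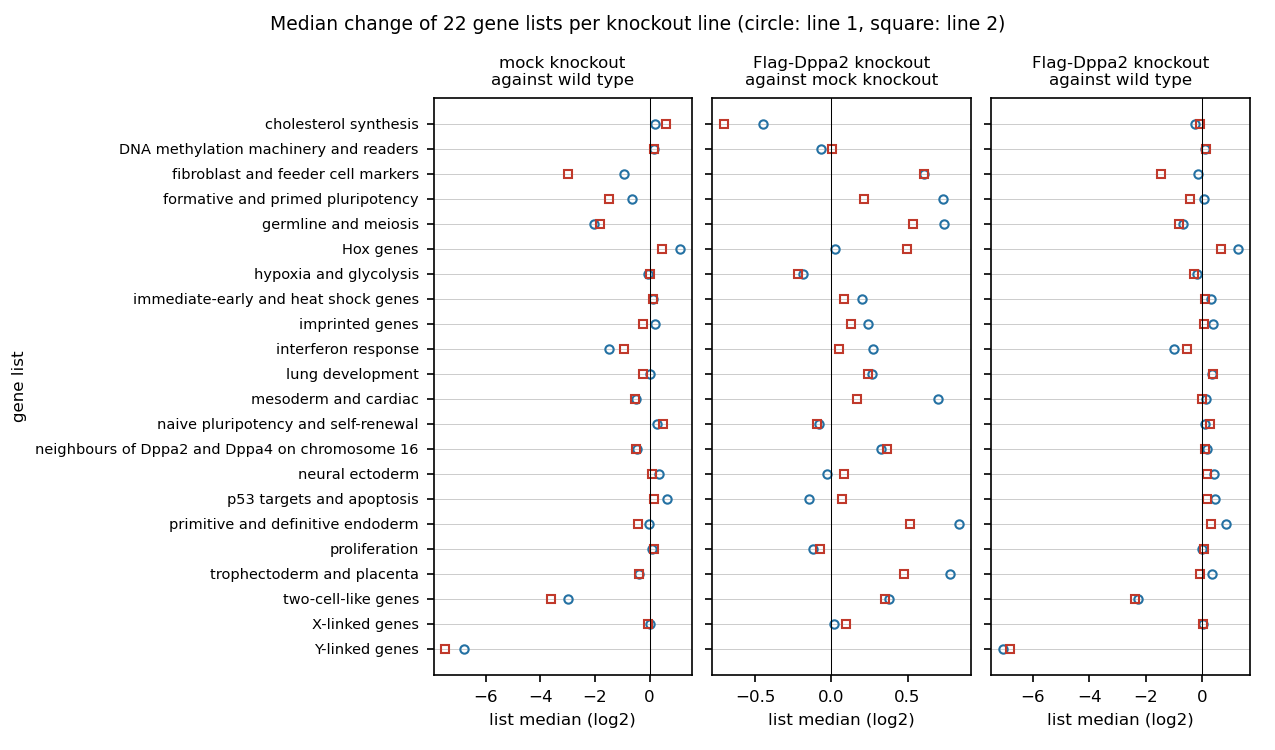
Median log2 difference (x axes) of the tested members of 22 gene lists (y axis) in each comparison, taken per knockout line, with line 1 as circles and line 2 as squares, against the wild-type mean in the outer panels. Y-linked genes are left out of the middle panel, where all lie below background, and the germline and two-cell-like medians lie below 0 in both lines against wild type.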

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

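Of the tests below, only the one on dim probes of the slides was chosen before its result was seen, and all others were chosen afterwards.

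In 11 list medians and 1 named gene, the 2 knockout lines lay on opposite sides of 0, which is what brought them here. The difference between the lines was not tested in any of them, since each line has 1 array per vector. Given as line 1 minus line 2, the differences for mock against wild type were 0.43 for imprinted genes, 0.28 for lung development genes, 0.0781 for X-linked genes and -0.0892 for hypoxia genes. For Flag-Dppa2 against mock they were -0.21 for p53 targets, -0.11 for neural ectoderm genes and -0.0755 for DNA methylation genes. For Flag-Dppa2 against wild type they were 0.49 for formative pluripotency, 0.41 for trophectoderm, 0.15 for mesoderm and -0.0878 for proliferation genes, and 1.32 for Nkx2-5. None of these lists passed its test in the comparison named, nor was Nkx2-5 called there.

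The genes lower in the mock knockout than in wild type include all 3 tested Y-linked genes, whose median with Flag-Dppa2 was still -6.92 against wild type, or -6.39 with genes below background at their bounds, both under the -1 set as the limit for knockout lines of another sex or lines that lost the Y chromosome. As the whole cause of the other lower genes, sex was set against the share of the fall regained with Flag-Dppa2 in the same lines. The median share was 0.542 over 539 genes (quartiles 0.257 and 0.837), and 0.424 for genes not called with Flag-Dppa2. Fall and return shared no array, but the genes were chosen as lower from both mock arrays, from which the return was also taken. That choice alone raises the share, by an amount that was not measured, so the share does not decide. A second active X chromosome is argued against by the X-linked median, which differed from the autosomal one by -0.030 (381 and 11412 genes). Sex stays open for the other lower genes. For the part of the fall that was not regained, the Dppa4 allele, the transduction and the level of Dppa2 made from the vector also stay open and untested.

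The changes of the mock knockout that turn back with Flag-Dppa2 were set against the slides, since the Flag-Dppa2 arrays lie on a slide of their own. Probes below background on all arrays of the first slide differed by a median of 0.224 on the second (14349 probes, quartiles 0.088 and 0.301). This argues against a general shift of dim probes as the whole cause. The genes changed back had a median of 2.38, but they were chosen for a rise in this same comparison, so the 2 medians are not alike. Slide effects at single dim probes stay open. For the covariance over all genes, the shared mock arrays as the whole cause are argued against by the value of -0.365 with no array shared. That value was not recomputed with normexp. It does not cover the genes called back, since the calls were not repeated on split mock arrays. Dppa2 itself lay higher by 2.20 with the vector, as its production from the vector predicts, though whether the probe reads the vector's sequence was not checked. Other differences between the slides cannot be told apart from the vector, as slide and group are confounded.

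Fibroblast and feeder cell markers lower in the mock knockout could reflect fewer fibroblast-type cells. If such cells had returned with Flag-Dppa2, the abundant markers would return together, but among the 5 brightest the lowest difference was -0.10 for Col1a1, with an SE of 1.00, beside 3.91 (SE 0.19) for Mmp2. That SE leaves the test open. If they were fewer in all knockout cultures, the markers would stay low with Flag-Dppa2: 9.09%, 1 of the 11 members that were 2-fold lower in both mock arrays, returned to over -0.5, and 9 stayed at or under -1. Cell composition and a change within the stem cells cannot be told apart here, for want of arrays.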

How the results depend on the processing

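Averaging the wild-type arrays, the cell line as a random block and the 4 knockout arrays with the block were chosen after the results were seen. Counts are limma calls in the order mock against wild type (892), Flag-Dppa2 against mock (119), Flag-Dppa2 against wild type (69) and changed back (110), and the covariance was -0.423.

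With the wild-type arrays averaged into 1 sample all 4 counts were 0, with 1696, 1072 and 1051 unadjusted p-values under 0.05, and Dppa2 was at -4.15 (adjusted p = 0.136) and 2.20 (0.177). Leaving out 1 array, which assumes that the lone array varies like the other groups, gave ranges of 0 to 709, 0 to 91, 0 to 3 and 0 to 88, a covariance of -0.629 to -0.365, Dppa2 at -4.19 to -4.10 and 2.00 to 2.40, and 20 to 36 list tests passed against 30. Without wild-type replicate 1 or 2 all 4 counts were 0 (1725 and 1736 unadjusted in the first, 1072 in the second, 1057 and 1104 in the third), and Dppa2 was not called (adjusted p = 0.116 and 0.132, then 0.177). Without mock replicate 1 they were 286 (28 higher and 258 lower), 29, 3 and 28, and without mock replicate 2 310 (34 and 276), 91, 3 and 88, with Dppa2 against mock at 2.15 (0.0968) and 2.24 (0.0808). Without Flag-Dppa2 replicate 1 or 2 the first count was 709 and the others 0 (2021 and 1806 unadjusted in the second, 3028 and 2519 in the third), with Dppa2 at 2.40 (0.0725) and 2.00 (0.0635). The list tests passed fell to 20 without Flag-Dppa2 replicate 1.

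The replicate block gave 390 (72 higher and 318 lower), 3, 0 (3031 unadjusted) and 3, and Dppa2 against mock at 2.20 (adjusted p = 0.0667). It ended no list test's call, and 7 gained one. Only the 2 groups compared gave 0 (1072 unadjusted) in the second and 3 in the third comparison. In the second, this is the same fit as with the wild-type arrays averaged or either of them left out. The 4 knockout arrays with the block gave 0 in the second (2601 unadjusted), and the cell line as a random block gave 1365 (870 and 495), 31 (4 and 27) and 357 (277 and 80) in the last 3. The slide as a block left 892, since the second slide is the Flag-Dppa2 group, and was not run for the other results, where it cannot be told apart from the group. Dppa2 had no other probe to test.

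Quantile normalization gave 156 (62 higher and 94 lower) in the third comparison, as did the series matrix. Normexp gave 45, 297 (144 and 153), 41 and a covariance of -0.130 in the last 4 results, and 1326 in the first. A floor for dim values gave 139 (42 and 97) in the third. No filter gave 305 (25 and 280), 37, 5 (0 and 5) and 37 over 18516 genes, and the filter on all 6 arrays 884 (457 and 427), 25, 18 (7 and 11), 25 and -0.181 over 11796 genes. The last filter drops every gene that fell below background in the mock arrays, which lowers the changed-back count by construction. Signal over background limits the folds of such genes to bounds. Every probe gave 110 in the third, the trend 1466 (709 and 757) in the first and 224 (128 and 96) in the third, and a 2-fold minimum 566 (122 and 444) in the first. The mean over probes and robust eBayes stayed within 1.5 times.

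Of 66 list tests, 30 passed as designed, 0 with an estimated correlation, 22 with fry, which asks whether the members differ from 0 rather than from other genes, 37 with the block, 29 with quantile normalization and 34 with wild type averaged. The 0 with an estimated correlation does not show that correlation removes the lists, since camera then has 3 residual degrees of freedom. For interferon genes in the third comparison the estimated correlation was 0.0003, under the preset, yet the camera p went from 0.00034 to 0.029. Cholesterol genes had an estimated correlation of 0.746 and passed fry in no comparison (adjusted p = 0.187, 0.098 and 0.464). With normexp the medians of passing tests shrank by over 1.5 times for interferon (-0.58), germline (-0.81), fibroblast (-0.56), two-cell-like (-1.32) and Y-linked genes (-3.27) in the first comparison, for mesoderm (0.20), germline (0.29), fibroblast (0.37), neighbour (0.22) and endoderm genes (0.36) in the second, and for Hox (0.42), lung (0.21), germline (-0.39), fibroblast (-0.44), two-cell-like (-1.23) and Y-linked genes (-3.36) in the third, and all of these kept their calls. Of 2242 alternative values of 240 named results, 1489 kept direction and side of the threshold, 684 lost it, 64 gained it and 5 changed sign: Nkx2-5 against wild type without Flag-Dppa2 replicate 1 (-0.38, in a range up to 0.94 without replicate 2), Taok3 with Flag-Dppa2 at another probe (0.58), Cdc6 in the knockout at another probe (0.31) and Acta2 against wild type at other probes (-2.02 and -1.89). For these the cause was not tested.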

Other observations

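Pou5f1, which encodes Oct4, stood at 2.84 in wild type, 3.62 ± 0.08 in mock and 5.10 ± 0.38 with Flag-Dppa2 (SD, n = 2). It was not called in any comparison (limma adjusted p = 0.052 for Flag-Dppa2 against wild type).

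The Dppa2 probe stayed below its wild-type level with Flag-Dppa2 (log2 difference -1.95), while Psma8 and Aga were not called against wild type with Flag-Dppa2 (-0.52 and 0.76). Of the two-cell-like genes, Usp17la, Gm428 and Tcstv1 were not well above background on any array of both knockout groups.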
